A study of Homo sapiens with 2 samples.

How the data were processed

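The data were 2 one-colour microarrays of RNA from U251 cells, an established human glioma cell line. One culture carried a lentiviral vector with the mature miR-218 sequence and the other the control vector, per the labels. Each group held 1 array, so no test between groups was made and no p-value was computed. The number of arrays limits the precision of every value.

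The authors deposited one scanner file per array, made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. Its spot values are intensity values of the Cy3 channel, per the file headers. The processed signal used here is an intensity from which Feature Extraction had subtracted a spatial background surface, per the file headers. The files also hold flags of other kinds for each spot, per the file headers, namely whether it was well above background, saturated or an outlier among its pixels or its replicate spots. The authors also deposited a value table on a log2 scale, whose making is not given in the sources used here. Set against the scanner files, its columns followed log2 of the processed signal, so that its scale and direction were settled. Its columns held the same set of values on both arrays to within 0.000324, as quantile normalization gives, and both medians were 4.68. It held 0 columns of other samples.

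The main values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Each processed signal was put on the log2 scale and the array's 75th percentile over non-control spots was subtracted. Control spots were left out, as were 286 outlier spots on the control array and 339 on the miR-218 array. Spots of one probe were averaged. A probe was called measured when most of its spots were well above background and none was saturated, and 0 spots were saturated on either array. A gene took the value of its probe with the highest mean level over both arrays, and was called measured when that probe was measured on both. The log2 ratio is miR-218 minus control throughout. A level is a log2 value relative to the array's 75th percentile, used to pick a gene's probe, to match random lists and to call genes dim or bright. It depends on the probe as well as on the transcript, so no gene's level was given against that of another gene.

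The arrays name probes by accession, and symbols were taken from a RefSeq table of assembly GCF_000001405.40 (GRCh38.p14). Of 42405 probes, 24826 matched a symbol, among them 23475 of the 24244 probes with a curated messenger RNA accession. The other 17579 probes stayed unnamed, 8263 of them probes for long intergenic RNAs. The array's genome build is not given in the sources used here, so no coordinates are printed, and the table served for names and for which genes neighbour each other.

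Where a gene was measured on one array and none of its probes was well above background on the other, only a bound was given. It set the bright array's value against the higher of the dim array's own value and its lowest signal among measured probes. Some probes above that lowest signal were not well above background. Bounds were computed in the main setting only and carry no error, so they are not strict limits. The error beside a log2 ratio is the SD from Feature Extraction's error model, which covers the spot measurement and not the spread between cultures.

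Before the data were examined, 20 gene lists and 7 cell type marker lists were fixed. For each list the median log2 ratio of its measured members was set against 10000 random lists of the same size, matched on mean level in 20 bins. Its percentile among them describes these arrays and does not test the conditions. A further 8 lists were written after the data had been examined. They hold genes of MHC class I antigen presentation, interferon ligands with receptors and transducers, nucleic acid sensors, smooth muscle contractile genes, secreted matrix of fibroblasts, TGF-beta targets, translation factors, and proteasome with other bright housekeeping genes.

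The rule for named genes was also fixed before the data were examined. It took the 12 highest and 12 lowest log2 ratios, leaving out a gene if another of its measured probes had the opposite sign. It took the 4 genes with the largest bound in each direction, and from each list up to 4 measured members with the largest absolute log2 ratio. It always took SLIT2, SLIT3, ROBO1, IKBKB, BMI1, LEF1, RICTOR, CDK6, GLCE and EGFR. Some genes that the rule takes are not reported here. Other genes named are said to have been chosen after their values were seen.

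The alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), median scaling, quantile normalization, loess centring with a span of 0.4 (statsmodels 0.14.6), the deposited value table, no filter on dim probes, a stricter filter, the median over a gene's probes, outlier spots kept, and thresholds of 1.5-fold and 3-fold. Scaling to 6 spike-in probes, scaling over probes detected on both arrays and a finer match of random lists to the 50 genes of nearest level were added after the data had been examined. The steps were tested on simulated data in which 200 of 12680 genes differed 4-fold between a simulated miR-218 and a simulated miR-control array. All of them (100%) passed the 2-fold threshold in each direction, and 0 other genes did. The simulated spread between arrays was 0.2 log2 units, against an SD of 0.52 for the measured log2 ratios. The simulated miR-218 array also took over the control array's flags, so no gene could be lost as dim. The simulation therefore checks the steps, and not how well differences are found in these arrays. Both arrays came from one slide and one scan, per the file headers, so neither could be fitted as a block. Genes with a miR-218 seed site in their 3' untranslated regions were not analysed here, since no such sequences were used. The microRNA itself was not measured, since the array carries probes for longer RNAs.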

Results

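Gene expression was measured in U251 cells, a human glioma line, after stable transduction with a lentiviral vector for miR-218 or with its control vector. MicroRNAs such as miR-218 lower the output of messenger RNAs that carry a matching site, and the comparison asks which transcripts differ with the microRNA. Each condition was represented by 1 array, so the differences have no replicate check. On the control array 53.7% of probes were well above background, against 50.3% on the miR-218 array. The 75th percentile of processed signal was 523 on the control array and 351 on the miR-218 array, and the median signal of negative control spots was 4.16 and 4.36. After scaling, 11998 of the 19062 genes with a probe were measured on both arrays.

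The most prominent difference was in the genes that interferon switches on, which had far lower values with miR-218. Of 25 interferon-stimulated genes on the array, 20 were measured on both arrays, and 20 of 20 lay at least 2-fold lower with miR-218. Their median log2 ratio was -4.60, a 24.2-fold difference, and single members ran from 7.58-fold to 141-fold lower. With normexp the median was -4.11. None of the 10000 level-matched random lists had a median as low, and 95% of them lay between -0.08 and 0.22. The antiviral GTPases MX2 and MX1 had log2 ratios of -7.14 ± 0.32 and -6.60 ± 0.21 (error model SD), and with normexp MX2 stood at -5.34. The RNA-binding antiviral proteins IFIT3, IFIT2 and IFIT1 stood at -6.34, -5.20 and -4.90, and IFI44L at -5.93. RSAD2 (viperin), an antiviral enzyme, was not well above background with miR-218 and lay at least 150-fold lower, and OAS1, which makes the second messenger of RNase L, at least 20.9-fold lower.

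Interferon genes made up much of the bottom of the ranking, with 7 of the 12 lowest, 15 of the 25 lowest and 19 of the 50 lowest genes on the fixed list. The 12 lowest log2 ratios also held IFITM1 (-6.89 ± 0.20), a membrane protein that restricts virus entry, the interferon-induced nucleotide kinase gene CMPK2 (-6.33), and OASL (-5.84), a member of the fixed list. The other 3 were LGALS9C (-5.20), KCNIP4, a potassium channel partner that lay 32.0-fold lower, and SLC15A3 (-4.97), a lysosomal peptide transporter. With normexp CMPK2 stood at -4.64, OASL at -4.84, LGALS9C at -4.49, KCNIP4 at -3.20 and SLC15A3 at -3.29. Among genes with only a bound, RTP4 lay at least 95.3-fold lower and TRANK1 at least 22.1-fold lower.

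In all, 362 genes were at least 2-fold lower with miR-218 and 132 genes at least 2-fold higher. At 8-fold the counts were 51 lower and 0 higher among genes measured on both arrays. The median log2 ratio of all measured genes was 0.07, with quartiles at -0.15 and 0.28. A further 60 genes had a bound of at least 2-fold lower and 64 of at least 2-fold higher. Of the 2-fold genes 73.3% were lower, against 83.6% under median scaling, 85.5% under loess centring, 86.3% with normexp background correction and 63.9% with spike-in scaling. Without the filter on dim probes the excess turned round, with 31.4% lower. Before scaling, negative control spots had similar medians on the control and miR-218 arrays (4.16 and 4.36). Scaling raised the miR-218 array by 0.57 log2 units against the control array, so probes at background lean upward by scaling alone. Median scaling moved the median of all measured genes to -0.04 and loess centring also to -0.04.

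Spots of one probe on one array differed little. Their median SD was 0.04 log2 units on either array. Of 5551 repeated probes on the control array, 5 differed at least 2-fold between their first and last spot (0.0901%), and 3 of 5292 did on the miR-218 array (0.0567%). Spots flagged as outliers among their replicate spots had been left out, which lowers these shares. Between the arrays, the averaged values of 282 of 5243 repeated probes differed at least 2-fold (5.38%). Where a gene had several measured probes, a probe of opposite sign was found for 7 of 52 genes lower and 2 of 17 genes higher.

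**Figure D1:**
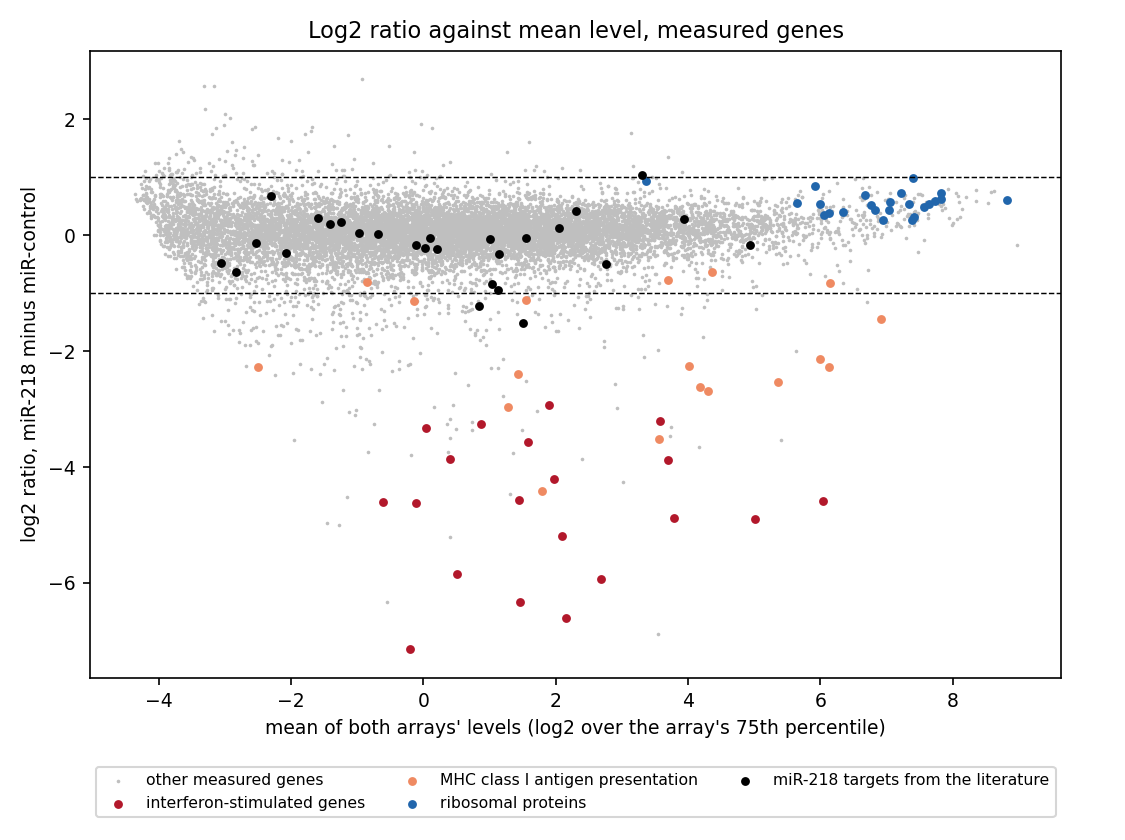
Log2 ratio (miR-218 minus miR-control) against the mean of both arrays' levels for the 11998 measured genes, with 4 lists coloured and dashed lines at 2-fold. The 20 interferon-stimulated genes lie between -7.14 and -2.92, and the 24 ribosomal protein genes lie above 0.

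The highest log2 ratios were smaller and mostly belonged to dim genes. ADRA1B, an alpha-1 adrenergic receptor, led with 2.69 ± 0.21, a 6.47-fold difference. It was followed by PGAP4 (2.57 ± 0.33), which modifies glycosylphosphatidylinositol anchors, and CLEC3A (2.57), a C-type lectin. ARAP2 (2.17), ZBTB16 (2.09), SEMA5A (2.02), ACO1 (1.92), KRT13 (1.90), PLAG1 (1.87), SYT12 (1.86), GLDC (1.85) and LINGO2 (1.85) completed the 12 highest. ZBTB16 and PLAG1 are zinc finger transcription factors, SEMA5A an axon guidance protein, ACO1 the cytosolic aconitase and GLDC an enzyme of glycine breakdown. Of the 132 genes at least 2-fold higher, 113 lay below the median level of measured genes. With normexp the log2 ratio of ADRA1B was 2.07, of PGAP4 1.23, of CLEC3A 1.32, of ARAP2 1.07, of ZBTB16 1.18, of SEMA5A 1.13, of KRT13 1.04 and of SYT12 1.16, and that of GLDC no longer reached 2-fold (0.99). SLITRK3, a synaptic adhesion protein, lay at least 13.5-fold higher, SAMD7 at least 11.3-fold, TRIM49 at least 5.64-fold and CLEC18C at least 5.46-fold, none being well above background in the control.

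**Figure D2:**
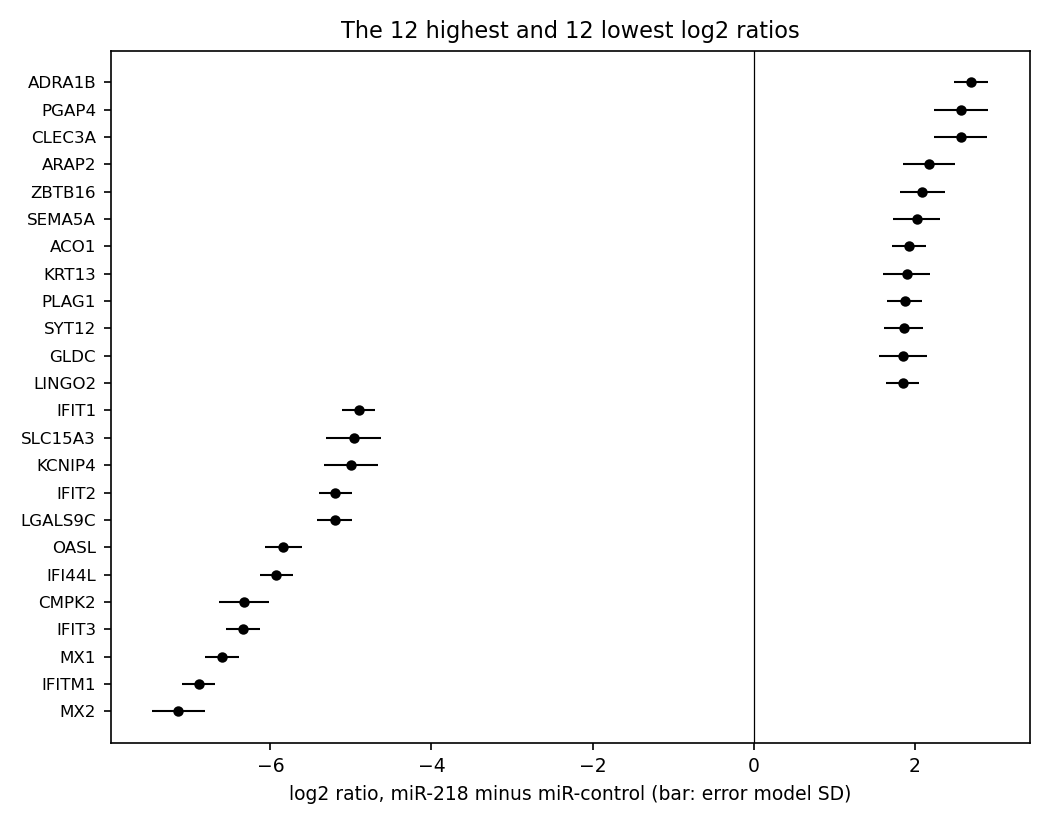
Log2 ratios (miR-218 minus miR-control) of the 12 highest and 12 lowest genes under the fixed rule, with 1 array per group and bars of 1 SD from the error model of the scanner software. The lowest runs to -7.14 (MX2) and the highest to 2.69 (ADRA1B).

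Genes named in the literature as targets of miR-218 were slightly lower as a group. A shift of this kind was not particular to them. Of the 20 fixed lists 8 lay outside their random ranges, and the interferon, hypoxia, matrix and NF-kB lists had lower medians. Of 27 measured targets 17 had negative log2 ratios and 10 positive ones, with a median of -0.14 against 0.06 for matched random lists, at percentile 0.52. PDGFRA, a growth factor receptor of glial cells, stood at -1.51 ± 0.20 and LEF1, a Wnt pathway transcription factor, at -1.21 ± 0.20. The gap junction gene GJA1 stood at -0.94. CDK6, a cell cycle kinase on the same list, had a higher value with miR-218 (1.04 ± 0.20), which was under 2-fold with loess centring (0.92), median scaling (0.94) and quantile normalization (0.99). Other listed targets lay close to 0, with RICTOR at -0.21, the NF-kB kinase gene IKBKB at -0.17, GLCE at -0.14, the Polycomb gene BMI1 at 0.05 and EGFR at 0.23, and the sign for BMI1 turned with median scaling and loess centring. ROBO1, the receptor of SLIT proteins, stood at -0.48 ± 0.28. With normexp the value of ROBO1 was 0.00 and that of GLCE 0.18.

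The genes that host miR-218 differed in opposite directions. SLIT3 had a lower value with miR-218 (-1.26 ± 0.20) and SLIT2 a higher one (0.76 ± 0.21). The SLIT-ROBO list as a whole, with 7 of 13 measured members above 0, had a median of 0.14 at percentile 78.9, and of -0.045 at percentile 17.2 with the stricter filter on dim probes. NCK2, an adaptor of that pathway, stood at 0.85.

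Several lists of matrix, inflammation and stress genes lay below matched random lists. The 18 hypoxia response genes had a median of -0.30, with 15 below 0, and none of the random lists was as low. The angiogenic factor VEGFA stood at -1.04, NDRG1 at -0.95 and ADM at -0.77, while the glycolytic enzyme gene ENO1 stood at 0.57 and at 0.33 with loess centring. VEGFA was under 2-fold with the median over its probes (-0.86) and with spike-in scaling (-0.97). Extracellular matrix genes had a median of -0.19 at percentile 0.03, with 15 of 23 below 0. COL1A1, a chain of type I collagen, was 14.6-fold lower (-3.87 ± 0.20) and the protease MMP7 8.22-fold lower (-3.04 ± 0.20), while THBS1 stood at -1.02 and at -0.95 with spike-in scaling. PLAU, the urokinase gene, had a higher value (0.99). NF-kB targets had a median of -0.24 at percentile 0.32, with 8 of 13 below 0. The chemokine CCL2 stood at -1.23, TNFAIP3 at -0.73 and IL6 at -0.61. With normexp the value of TNFAIP3 was -0.04. Heparan sulfate genes had a median of -0.12 at percentile 1.88, with 13 of 18 below 0, led by the sulfatase SULF2 (-1.20). The unfolded protein and amino acid stress list had a median of -0.13 at percentile 0.83, with 11 of 18 below 0. CHAC1, a glutathione-degrading enzyme of that list, stood at -0.80, and the phosphatase subunit gene PPP1R15A at 0.69.

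Ribosomal protein genes had higher values with miR-218. All 24 were measured and 24 of 24 lay above 0, none of them by 2-fold, with a median of 0.54 and matched random lists between 0.06 and 0.33. With the finer match the random lists lay higher, between 0.20 and 0.45. RPLP0 stood at 0.98 ± 0.20, RPS3 at 0.93 and RPL7 at 0.86. RPLP0 stood at 0.65 with quantile normalization and in the deposited table, and at 0.64 with loess centring. Under the other scalings the median ran from 0.17 to 0.61. Reference genes often used for scaling had a median of 0.25 at percentile 84.6, with EEF1A1 at 0.79 and ACTB at 0.55. EEF1A1 stood at 0.32 with quantile normalization and in the deposited table, and at 0.41 with loess centring. The sign for ACTB turned with quantile normalization (-0.045) and in the deposited table (-0.016). B2M, the light chain of MHC class I and a reference gene in that list, stood at -2.13 ± 0.20. The reference list's median turned negative (-0.07) in the lowest scaling.

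The other lists lay inside the central 95% of their matched random lists in the main setting. Cell cycle genes had a median of 0.11 at percentile 74.5, with 23 of 33 above 0, led after CDK6 by the cyclin CCND1 (0.68) and CDC20 (0.67). Wnt targets had a median of 0.14, with the secreted Wnt inhibitor DKK1 at 1.19 beside LEF1. Receptor tyrosine kinase genes had a median of 0.09, with PDGFRA at -1.51, IGF1R at 1.13 and AXL at 0.89. The p53 and apoptosis list had a median of 0.02, with CASP8 at 1.38 and ZMAT3 at 1.07, and both were under 2-fold with normexp (0.91 and 0.76). Integrin genes had a median of 0.15, with ITGA5 at -1.09 and ITGB3 at -1.03, the latter -0.71 with normexp and -0.96 with spike-in scaling, and the list lay above its random range with the stricter filter on dim probes (percentile 97.6). Mesenchymal glioblastoma markers had a median of -0.05 at percentile 2.88, outside the random range in 5 of 11 alternatives and with the finer match (percentile 0.97), with SNAI2 at -0.97 (-0.62 with normexp) and VIM at 0.72 (0.32 with quantile normalization and in the deposited table, 0.36 with loess centring). Neural stem and proneural markers had a median of 0.01, with the Notch target HEY1 at -1.45. Polycomb genes had a median of -0.07, cholesterol and fatty acid synthesis genes 0.13 and microRNA machinery genes 0.13, with AGO2 at 0.57. The signs of the mesenchymal, neural stem, p53 and receptor kinase medians changed between scalings.

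**Figure D3:**
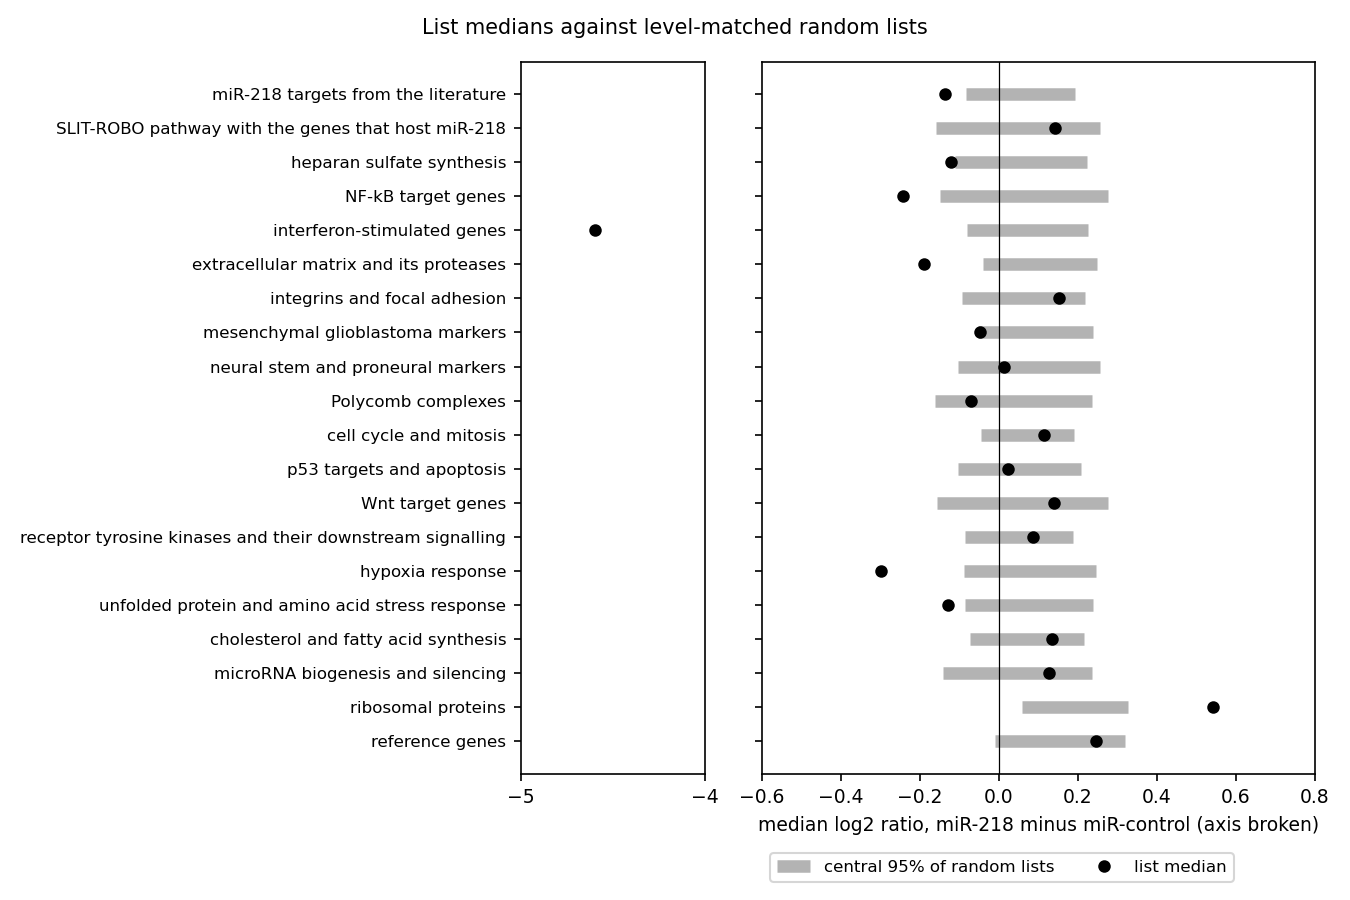
Median log2 ratio (miR-218 minus miR-control) of each of the 20 fixed lists (points) with the central 95% of 10000 level-matched random lists (grey bars), 1 array per group, on a broken axis. The interferon list lies at -4.60 and the ribosomal list at 0.54, and 8 lists lie outside their grey bars.

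Markers of other cell types were measured in part. Of 10 fibroblast and pericyte markers 4 were measured, with a median of -1.28 (-0.69 in the highest of 11 alternatives) and 4 of 4 below 0, among them COL1A1. DCN, LUM and COL3A1, which fibroblasts make in quantity, were not well above background on either array. COL1A2, PDGFRB, THY1 and FAP, on the same list, were well above background on the control array. The median was -0.47 over 6 astrocyte markers and -0.60 over 3 oligodendrocyte lineage markers, the latter 0.01 with normexp. Over 5 leukocyte markers it was -0.41, over 5 neuronal markers 0.21 and over 5 epithelial markers 0.15, which turned negative with loess centring. Without the filter on dim probes the signs turned for the astrocyte (0.20), oligodendrocyte lineage (0.54) and leukocyte (0.37) medians, and the leukocyte list lay outside its random range in 5 of 10 alternatives. The single measured endothelial marker stood at 0.31.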

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

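These values lie outside the named genes. Among 5536 unnamed probes measured on both arrays, 199 (3.59%) were at least 2-fold higher on the miR-218 array than on the control array, and 76 (1.37%) were at least 2-fold lower. Of the 2627 measured probes for long intergenic RNAs, 126 were at least 2-fold higher and 24 at least 2-fold lower. They drew attention because the comparisons of named genes do not use them, and no explanation was tested. The counts are for the main setting only. In it the lowest level of a measured probe was -4.80 on the control array and -4.18 on the miR-218 array, which bears on dim probes. Among named genes, those at least 2-fold higher were mostly dim, and normexp cut their number from 132 to 36.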

How the results depend on the processing

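Spike-in scaling, scaling over detected probes, the finer match and the count without interferon lists were chosen after the data were seen. Genes at least 2-fold higher, 132 in the main setting, numbered 36 with normexp, 84 with median scaling, 74 with loess centring and 1365 without the filter on dim probes. They numbered 32 with the stricter filter, which kept only probes above the median level of measured probes, 771 at 1.5-fold and 23 at 3-fold. Genes at least 2-fold lower, 362 in the main setting, numbered 227 with normexp, 625 without the filter on dim probes, 189 with the stricter filter, 824 at 1.5-fold and 162 at 3-fold, and 328 without the interferon and MHC class I lists. Fewer or more genes pass other thresholds and filters by construction, and for the scalings the cause was not tested. The median of the miR-218 targets was -0.054 with normexp, -0.24 with median scaling, -0.25 with loess centring and -0.062 without the filter, and it lay below the central 95% of random lists in 11 of 11 alternatives. The interferon median was -4.11 with normexp, -4.71 with median scaling, -4.68 with quantile normalization, -4.69 with loess centring and -4.68 in the deposited table. Without the filter on dim probes the marker medians turned positive for astrocytes (0.20), oligodendrocyte lineage (0.54) and leukocytes (0.37), as did the added fibroblast matrix list (0.075), and the oligodendrocyte median was 0.011 with normexp. Probes at background lean upward by scaling alone, and how far this accounts for the turned medians was not tested. Other lists gave 273 medians that stayed within the SD of random medians and 83 that moved further. Of 1291 values of 121 named genes under alternatives, 1222 moved by less than the error model's SD and 0 genes at 2-fold changed sign. Of 59 named genes at 2-fold, 8 were under it in some alternative. With the finer match 9 of 20 fixed lists lay outside the random range in place of 8, the mesenchymal markers being the addition. Signal over background limits dim genes, which normexp draws towards 0. The slide as a block and the seed sites were not run. No paired analysis was possible because each group held 1 array.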

Other observations

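Every test below was chosen after the values were seen, except the loess test of the ribosomal genes. Genes of MHC class I antigen presentation, a list added after the data were examined, followed the interferon-stimulated genes. All 18 had lower values with miR-218, 14 of them at least 2-fold, with a median log2 ratio of -2.26. PSMB9, an immunoproteasome subunit, stood at -4.41, the peptide transporter gene TAP1 at -3.51, and HLA-C and HLA-B at -2.68 and -2.26. An added list of nucleic acid sensors had a median of -1.93 (-0.99 in the highest of 11 alternatives), with TLR3 at -3.01 (-2.11 with normexp) and EIF2AK2 at -2.11. The transducers IRF9 and STAT2 stood at -1.80 and -1.76, while the transducer kinase gene JAK1 stood at 0.56. The receptor genes IFNAR1 and IFNAR2 stood at 0.10 and 0.13, the sign for IFNAR1 turning with median scaling. The list of ligands, receptors and transducers had a median of -0.10, with 4 of 14 measured members at least 2-fold lower. Its median was positive with normexp (0.048) and without the filter on dim probes (0.090), and lay below its random range with the stricter filter (-0.47). Genes named here outside the fixed rule were chosen after their values were seen. They also include the brighter genes KRT15 (1.76), CKB (1.60) and PMEPA1 (1.36), and the glutamate transporter gene SLC1A3 (-1.65). The added list of TGF-beta targets had a median of 0.01, whose sign turned in some scalings.

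The interferon pattern was weighed against array effects, leukocytes and the state of the control culture. Under 5 other scalings the highest log2 ratio of any measured list member was -2.75, which argues against scaling. The lowest ratio of a leukocyte marker was -1.19 (CD68), against -2.92 for the highest of the interferon list. This was the last of 3 forms of that test, and it cannot decide on leukocytes. A dim marker had little room for so low a ratio, since no measured probe lay below -4.18 on the miR-218 array. Of 5 measured leukocyte markers 3 were lower, 2 of them at least 2-fold, and 2, PTPRC (0.89) and TYROBP (0.37), were higher, all 5 lying below the median level of measured genes. The first form set levels of different probes against each other and was dropped, and the second counted abundant leukocyte genes well above background on the control array, of which TYROBP was 1 of 2. Whether miR-218 lowered these genes or the control culture had an interferon response for other reasons, such as its vector, cannot be told apart with 1 culture per group. On the control array 2 interferon genes (IFNB1 and IFNE) were well above background, and IFNE also on the other. IFNB1 lay near the floor of the control array, at -4.58 against a lowest measured level of -4.80. The IFNB1 level also lay below the lowest measured level of the miR-218 array (-4.18). Its bound of 0.76-fold therefore could not have shown a decrease.

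The higher ribosomal values were weighed against an intensity trend and RNA quality. After loess centring the list's median was still 0.20, above the central 95% of its random lists, and the uncentred median lay at percentile 99.9 with the finer match. From a mean level of 5 to 7.5, the median was 0.48 for 62 genes whose symbols begin with RPL or RPS, on or off the fixed list, and 0.17 for 335 others. Above 7.5 the gap was 0.047 (19 against 24 genes), so for the brightest genes an intensity trend may account for the values. Respiratory chain genes are also short, and the 7 measured lay -0.50 from the ribosomal median. For these 7 genes that argues against a general gain of short transcripts. They were not matched on level to the ribosomal list, whose random lists had a median of 0.20, or 0.32 with the finer match. Proteasome with other housekeeping genes had a median of 0.12, negative after loess centring, against 0.45 for translation factors. A difference tied to miR-218 stays open.

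COL1A1 (-3.87), ACTG2 (-3.21), CNN1 (-2.17) and ACTA2 (-1.60) were lower together, a set picked after the values were seen, while of 9 measured genes on the added smooth muscle list, which holds the last 3, 7 were lower and 2 higher, with a median of -0.64. Whether fibroblasts in the control culture brought them cannot be told apart: of the 8 other markers on the fixed fibroblast and pericyte list, 4 (COL1A2, PDGFRB, THY1 and FAP) were well above background on the control array, and DCN, LUM, COL3A1 and RGS5 were not. FAP was at least 2.54-fold lower with miR-218. PDGFRB lay near the floor of the control array, at -4.32 against a lowest measured level of -4.80. The PDGFRB level also lay below the lowest measured level of the miR-218 array (-4.18), so its bound could not have shown a decrease. An earlier form of this test, on genes picked after their levels were seen, was dropped. Under 5 other scalings the highest ratio of the 4 genes was -1.23, which argues against scaling. A difference between the cultures, with or without a part of miR-218, stays open as a hypothesis.

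A further hypothesis was that the cultures differ in copy number or chromatin over stretches of the genome. Across 11973 pairs of measured neighbouring genes, Spearman's rho of the log2 ratios was 0.11, against -0.03 to 0.03 in 1000 random orders of the genes. Without 2-fold genes and the interferon and MHC lists it was 0.09 over 11037 pairs. Genes are not independent replicates, and related neighbours that share probes or regulation could also give such a value.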
